A study of Mus musculus with 8 samples.

How the data were processed

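Gene expression was measured in retinas of male C57BL/6 mice that were 6 weeks old at the start and received saline or MPTP, a neurotoxin whose metabolite MPP+ enters cells through the dopamine transporter and inhibits complex I of the mitochondrial respiratory chain. Retinas were taken at 1 week (7 days) or 4 weeks (28 days), which gives 4 groups with 2 arrays each. Per the labels, each group had 6 mice, and each array received RNA pooled from 4 retinas, so the 2 arrays of a group hold 8 of its 12 retinas. The labels do not say whether the pools of a group came from separate mice, and p-values here measure only the spread between these arrays. Total RNA was isolated with a column kit, and 100 ng was amplified by the SPIA method and labelled with biotin.

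The deposited values are in log2 units and were made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes, which give no version. RMA normalizes across arrays and gives 1 value per probe set. Background settings, hybridization dates and scan batches are not given in the sources used here. The scanned array images were not used here. For arrays, their number limits the precision.

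The table holds 28944 probe sets, of which 23410 carry an annotation and 21789 name exactly 1 gene. Probe sets with several genes (1621) and those without a gene entry (5534) were left out of the comparisons of genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was kept, which left 19938 genes. No filter on dim probe sets was applied in the reported values. Of the probe sets kept, 91 name a symbol without an entry in the RefSeq gene names used as a second source of names. Genome positions and gene lengths were not used here.

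Each gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes, two-sided). A model with a mean per group over all 8 arrays, with 4 residual degrees of freedom, gave the MPTP effect at 1 week, the MPTP effect at 4 weeks, the difference of these effects, and the change with time in the saline and in the MPTP groups. A second model with time and treatment as additive terms, with 5 residual degrees of freedom, gave the MPTP effect over both times from 4 arrays against 4. The p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. All differences are log2 fold changes followed by the standard error of the limma fit (the moderated spread shared by the groups), and n is 2 arrays per group, or 4 per treatment over both times. Genes changed 1.5-fold were counted when the unadjusted p was under 0.05 and no array of a group overlapped with the other group. That count describes size and is not a test.

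The choice of tests, gene lists, named genes and most alternatives was made before the data were examined. In all, 50 gene lists were fixed for mitochondrial, stress, inflammatory, neuronal, glial and other-tissue genes. Of these, 48 were tested with camera of limma at a preset correlation of 0.01 between genes, two-sided, and adjusted over the lists of a comparison. The minimum was 5 measured members, which 1 list missed, and 1 list had no measured member. Camera with an estimated correlation and fry (which tests whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes) were run beside it. The named genes are the 10 highest and 10 lowest log2 fold changes at 1 and at 4 weeks, and the 5 highest and 5 lowest in the other comparisons, among genes without overlap between groups. Genes at an adjusted p under 0.05 came first, and open places went to genes at unadjusted p under 0.05. Predicted-model and clone names, olfactory and vomeronasal receptors and microRNAs were passed over. A fixed set of dopamine system and cell marker genes was reported whatever its values. In each gene list described, the members with the smallest unadjusted p are the examples.

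The alternatives were quantile normalization, centring of each array on its median, a filter that keeps genes above percentile 50 of the mean signal, all probe sets or the mean of a gene's probe sets, an eBayes fit with trend and robust settings, a fit of only the groups compared, the array number as a block, each array left out in turn, the other set tests, and lists without members shared with other tissues. Chosen after seeing the data were cyclic loess normalization, leaving out the 2 arrays that stand apart, a block with exchanged numbers, and exact permutation tests on the mean signal of a list per array. Splits of the 8 arrays into other groups of 4 and 4 were fitted with time as a term, 35 in all with the real one, except that the split equal to time was fitted without that term. The code was tested on simulated data with known changes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.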

Results

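The data are 8 arrays of mouse retina in 4 groups, saline and MPTP at 1 week and at 4 weeks after treatment, with 2 arrays per group and a pool of 4 retinas on each array. Signal was measured for 28944 probe sets, and 19938 genes were compared. The title and labels set short-term against long-term regulation of retinal genes by MPTP, and the comparisons follow that design.

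The largest differences between arrays did not follow treatment or time. The first principal component held 38.3% of the variance and set apart saline 1 week array 2 (score 15.7) and MPTP 1 week array 1 (score 19.1) from the other 6 arrays, whose scores lay between -9.39 and -0.39. These 2 arrays also had the widest interquartile range of log2 signal, 2.08 each, against 1.84 to 1.95 in the others. Each correlated best with the other, at r = 0.995 across genes. Markers of other eye tissues differed between arrays too. The mean signal of the lens list was 7.51 in MPTP 1 week array 2 and between 6.66 and 7.16 in the other 7 arrays. The retinal pigment epithelium list was highest in the same array too, against means of 7.06 to 7.41 in the others.

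**Figure D1:**
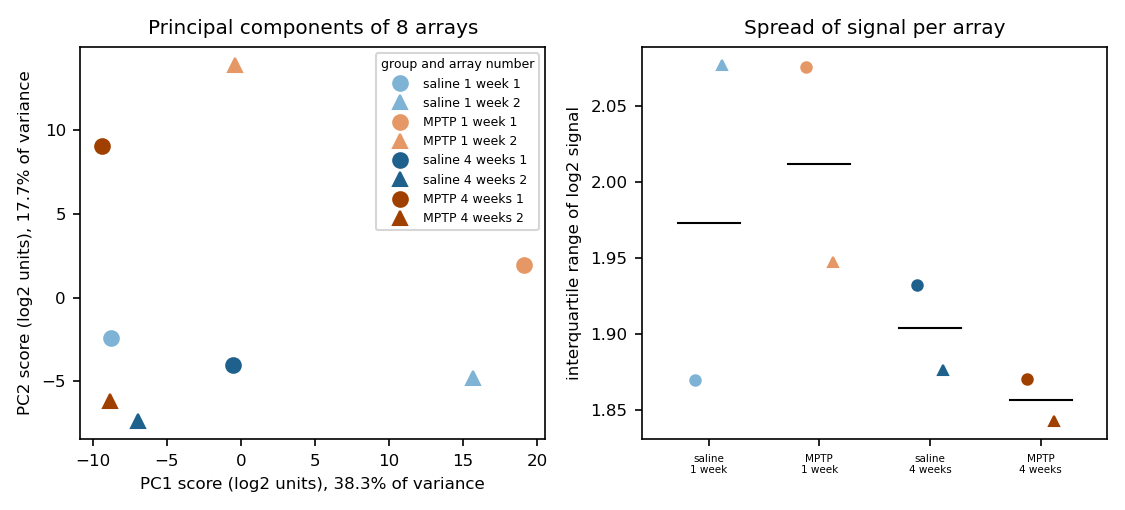
Left, scores of the 8 arrays on the first 2 principal components of log2 signal (38.3% and 17.7% of the variance); right, interquartile range of log2 signal per array by group, with a line at the group mean (circles, array 1; triangles, array 2). Saline 1 week array 2 and MPTP 1 week array 1 lie at 15.7 and 19.1 on the first component, and the other 6 lie between -9.39 and -0.39.

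MPTP against saline at 1 week asks for the early response. Subunits of the proteasome, ribosomal proteins and nuclear-encoded subunits of the respiratory chain had slightly higher signal in MPTP retinas, and so did interferon response genes, by camera with a preset correlation. These calls did not hold with an estimated correlation (adjusted p = 0.977 for the smallest) or after quantile or cyclic loess normalization. Among single genes, Ufm1, a ubiquitin-like protein modifier, stood 0.60 ± 0.13 higher, and Rlbp1, the retinaldehyde-binding protein of Mueller glia and pigment epithelium (probe set 10564726), stood at -0.52 ± 0.11. No single gene passed the adjusted threshold.

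Of the 31 proteasome subunits measured, 25 were above 0 with a median of 0.11 (camera adjusted p = 1.33e-04), for example Psmb1 at 0.23 ± 0.09 and Psmc1 at 0.22 ± 0.10. Of 26 ribosomal proteins, 20 were above 0 with a median of 0.11 (adjusted p = 1.33e-04). Examples were Rpl19 at 0.27 ± 0.08 and Rpl7 at 0.27 ± 0.09. The 35 complex I subunits had a median of 0.08 with 27 above 0 (adjusted p = 0.00194), with Ndufb5 at 0.34 ± 0.10 and Ndufa2 at 0.19 ± 0.10. The 37 subunits of complexes II to V had a median of 0.07 with 26 above 0 (adjusted p = 0.00194). Among them were Uqcrb at 0.35 ± 0.09, Uqcrh at 0.36 ± 0.10, Atp5h at 0.25 ± 0.09 and Cox5a at 0.25 ± 0.09. The 25 interferon response genes had a median of 0.07 with 16 above 0 (adjusted p = 0.0377). Its examples were Xaf1 at 0.38 ± 0.15, Oasl2 at 0.43 ± 0.20, Ifit1 at 0.51 ± 0.23 and Ifit3 at 0.48 ± 0.23. None of these 5 lists passed with an estimated correlation (adjusted p = 0.977 for the smallest), and with fry the smallest adjusted p was 0.946. After quantile or cyclic loess normalization none of the 5 passed. Leaving out 1 array of this time ended the calls of complex I (without saline array 1, adjusted p = 0.0599, or MPTP array 2, 0.0783), of complexes II to V (without saline array 2, 0.0912, or MPTP array 2, 0.0997) and of the interferon response (without saline array 1, 0.439, MPTP array 1, 0.120, or MPTP array 2, 0.0997). Beside these lists, MPTP 1 week array 2 had the highest lens and pigment epithelium signal of all arrays, with Crybb3 at 0.42 ± 0.15 and Rpe65 at 0.61 ± 0.40 in this comparison.

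The genes with the highest fold changes at 1 week were Rny1, a small Y RNA, at 0.73 ± 0.26, Clec2d at 0.69 ± 0.16, Ufm1, and Zfp763 at 0.59 ± 0.12. They were followed by Rtp4, an interferon-induced gene, at 0.57 ± 0.10, Tc2n at 0.55 ± 0.16, Zfp931 at 0.54 ± 0.24, Zfp229 at 0.50 ± 0.22, Ciart, a repressor of the circadian clock, at 0.50 ± 0.16, and Tmem229b at 0.49 ± 0.09. The lowest were Glipr1l1 at -0.68 ± 0.09, Cyp2c67 at -0.63 ± 0.10, Trav7d-4 at -0.62 ± 0.13, Samt2b at -0.60 ± 0.25, and Ifna12, a type I interferon, at -0.58 ± 0.12. They were followed by Rlbp1, Fsip2 at -0.52 ± 0.12, Naip5, an inflammasome sensor, at -0.47 ± 0.12, Tmem236 at -0.47 ± 0.11, and Cd300ld at -0.47 ± 0.10. The value of Rny1 rests on MPTP array 2, without which it was 0.21, against 1.26 without MPTP array 1. Several of the lowest genes were among the dimmest, with Glipr1l1 at percentile 1.54 of the mean signal, Cyp2c67 at 1.27, Trav7d-4 at 1.33 and Naip5 at 4.07. By contrast Rlbp1 stood at percentile 84.5 and Tmem229b at 91.5. Among the visual cycle genes and the Mueller glia genes, Rlbp1 passed when adjusted over the list alone, 1 gene in each list and none over all genes, and no other member passed. The visual cycle list had a median of 0.09 with 10 of 16 above 0 (camera adjusted p = 0.796), with Rdh12 at -0.21 ± 0.09, and the Mueller glia list a median of -0.02 with 11 above and 11 below 0 (adjusted p = 0.548), with Cd9 at -0.36 ± 0.13 and Dkk3 at -0.40 ± 0.15.

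By limma 0 of 19938 genes passed at 1 week (smallest adjusted p = 0.275, Glipr1l1), and 842 genes (4.22%, against 5% expected by chance) had an unadjusted p under 0.05, 372 higher and 470 lower. Of these, 13 had changed 1.5-fold without overlap, 6 higher and 7 lower, and 26.3% of all genes had no overlap against 33.3% by chance. The other 2 ways to divide the 4 arrays of this time into pairs gave 544 and 4235 genes at unadjusted p under 0.05, and the higher count came from setting the 2 arrays that stand apart against the other 2. Without those 2 arrays, 0 genes passed, 1698 had an unadjusted p under 0.05, 138 had changed 1.5-fold and 11 lists were called, but the proteasome list was not (median 0.05, adjusted p = 0.171).

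The genes of the dopamine system had small differences. Th, the rate-limiting enzyme of dopamine synthesis (probe set 10569370), stood at -0.16 ± 0.09 at 1 week and at -0.02 ± 0.09 at 4 weeks. In the same order, the dopamine transporter Slc6a3 stood at -0.09 ± 0.14 and 0.13 ± 0.14, Ddc at -0.05 ± 0.11 and -0.01 ± 0.11, and the vesicular transporter Slc18a2 at -0.06 ± 0.09 and -0.07 ± 0.09. The dopamine receptors Drd1 (-0.05 ± 0.09 and 0.05 ± 0.09), Drd2 (0.06 ± 0.09 and 0.02 ± 0.09) and Drd4 (0.0026 ± 0.09 and -0.16 ± 0.09) did not pass either. The small value of Drd4 at 1 week had the opposite sign, -0.02, after quantile or cyclic loess normalization. Th, Slc18a2, Slc6a3 and Ddc were dim, at percentiles 47.8, 38.2, 37.1 and 19.3 of the mean signal. Drd1, Drd2 and Drd4 stood at 83.7, 86.8 and 88.8. For the dim genes a small difference does not show that they were unaffected. Among cell markers, the glial Gfap stood at -0.10 ± 0.12 and 0.12 ± 0.12, and the microglial Aif1 at 0.12 ± 0.16 and 0.04 ± 0.16. These 2 were dim as well, at percentiles 40.4 and 17.7. The ganglion cell marker Thy1 stood at -0.08 ± 0.09 and 0.02 ± 0.09, and the short-wave cone opsin Opn1sw at -0.0093 ± 0.09 and -0.0084 ± 0.09. Of 18 genes of dopamine synthesis, storage and uptake, 6 were above 0 and 12 below at 1 week with a median of -0.04 (camera adjusted p = 0.548), and at 4 weeks the median was 0.02 (adjusted p = 0.588). The median of the Parkinson disease genes was 0.0013 at 1 week and -0.02 at 4 weeks.

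**Figure D2:**
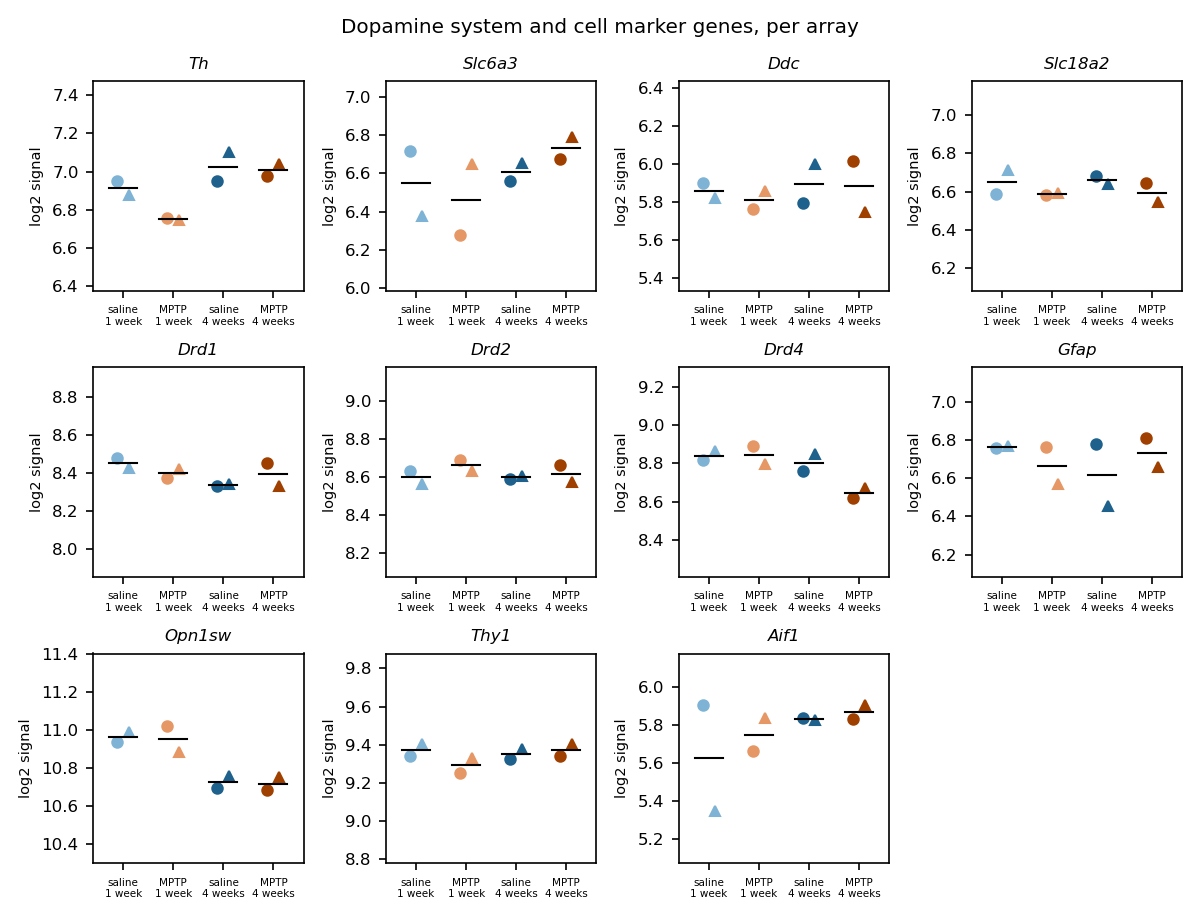
Log2 signal per array of the dopamine system and cell marker genes in the 4 groups (circles, array 1; triangles, array 2; lines, mean of the 2 arrays; each panel spans the same range of log2 units). For Th the MPTP arrays stood at -0.16 ± 0.09 from saline at 1 week and at -0.02 ± 0.09 at 4 weeks.

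MPTP against saline at 4 weeks asks for the late response. Subunits of complexes II to V of the respiratory chain had slightly higher signal in MPTP retinas, with 31 of 37 above 0 and a median of 0.06, a call lost with an estimated correlation (adjusted p = 0.988). Dio2, the deiodinase that activates thyroid hormone, stood at -0.42 ± 0.14 and Rlbp1 at -0.28 ± 0.11. A single MPTP array carried most of each difference. Dio2 was 6.72 and 7.21 in MPTP arrays 1 and 2, against 7.36 and 7.41 in saline. Rlbp1 was 8.44 and 8.16, against 8.59 and 8.58. No single gene passed the adjusted threshold, and most genes with the largest fold changes had dim signal.

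The list of complexes II to V was the only list called of 48 at 4 weeks (camera adjusted p = 0.00204), with Uqcrh at 0.32 ± 0.10, Uqcrb at 0.19 ± 0.09, Cox6c at 0.20 ± 0.09 and Cox7b at 0.28 ± 0.14. It did not pass with an estimated correlation (adjusted p = 0.988), and with fry the smallest adjusted p of any list was 0.946. It also did not pass without saline 4 weeks array 2 (median 0.04, adjusted p = 0.172) or without MPTP 4 weeks array 1 (median 0.03, adjusted p = 0.333). The medians of lists that describe glia and immune cells were 0.09 for Mueller gliosis and acute glial response and 0.06 for microglia and macrophages, against -0.07 and -0.02 at 1 week, and none of these passed. The lens list had a median of 0.05 (adjusted p = 0.402) at 4 weeks and 0.09 (adjusted p = 0.145) at 1 week.

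The genes with the highest fold changes at 4 weeks were Fam136a at 0.52 ± 0.16, Rdh7 at 0.49 ± 0.19, Hsd3b1 at 0.49 ± 0.10, Mrgpra6 at 0.48 ± 0.15 and Rnf125 at 0.47 ± 0.14. They were followed by Teddm3 at 0.46 ± 0.14, Klrc3 at 0.45 ± 0.18, Sult3a2 at 0.45 ± 0.13, the defensin Defb14 at 0.45 ± 0.12, and Ccr1l1 at 0.43 ± 0.18. The lowest were Ssxb3 at -0.55 ± 0.14, Cyp2a12 at -0.51 ± 0.19, Chil3 at -0.47 ± 0.14, the mitotic kinesin Kif4 at -0.46 ± 0.14, and Prpmp5 at -0.46 ± 0.15. Next came the potassium channel Kcnj14 at -0.45 ± 0.17, the complement protease C1s1 at -0.43 ± 0.11, Dio2, Il1f8, which encodes a cytokine of the interleukin 36 group, at -0.39 ± 0.15, and Dok6 at -0.38 ± 0.13. Klrc3, Sult3a2 and Mrgpra6 stood at percentiles 0.732, 0.351 and 1.04 of the mean signal, and Dio2 and Kcnj14 at 56.6 and 56.0.

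By limma 0 genes passed at 4 weeks (smallest adjusted p = 0.645, Gm5039), and 381 genes (1.91%) had an unadjusted p under 0.05, 219 higher and 162 lower. In all, 2 genes had changed 1.5-fold without overlap, the vomeronasal receptor Vmn1r201 (0.63 ± 0.09) and the small nucleolar RNA Snord61 (-0.60 ± 0.19), both named after their values were seen. Of all genes 35.3% had no overlap against 33.3% by chance. The other 2 ways to pair the 4 arrays of this time gave 602 and 298 genes at unadjusted p under 0.05. With the spread taken without the 2 arrays that stand apart, 0 genes passed, 942 had an unadjusted p under 0.05, 2 had changed 1.5-fold and 1 list was called.

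**Figure D3:**
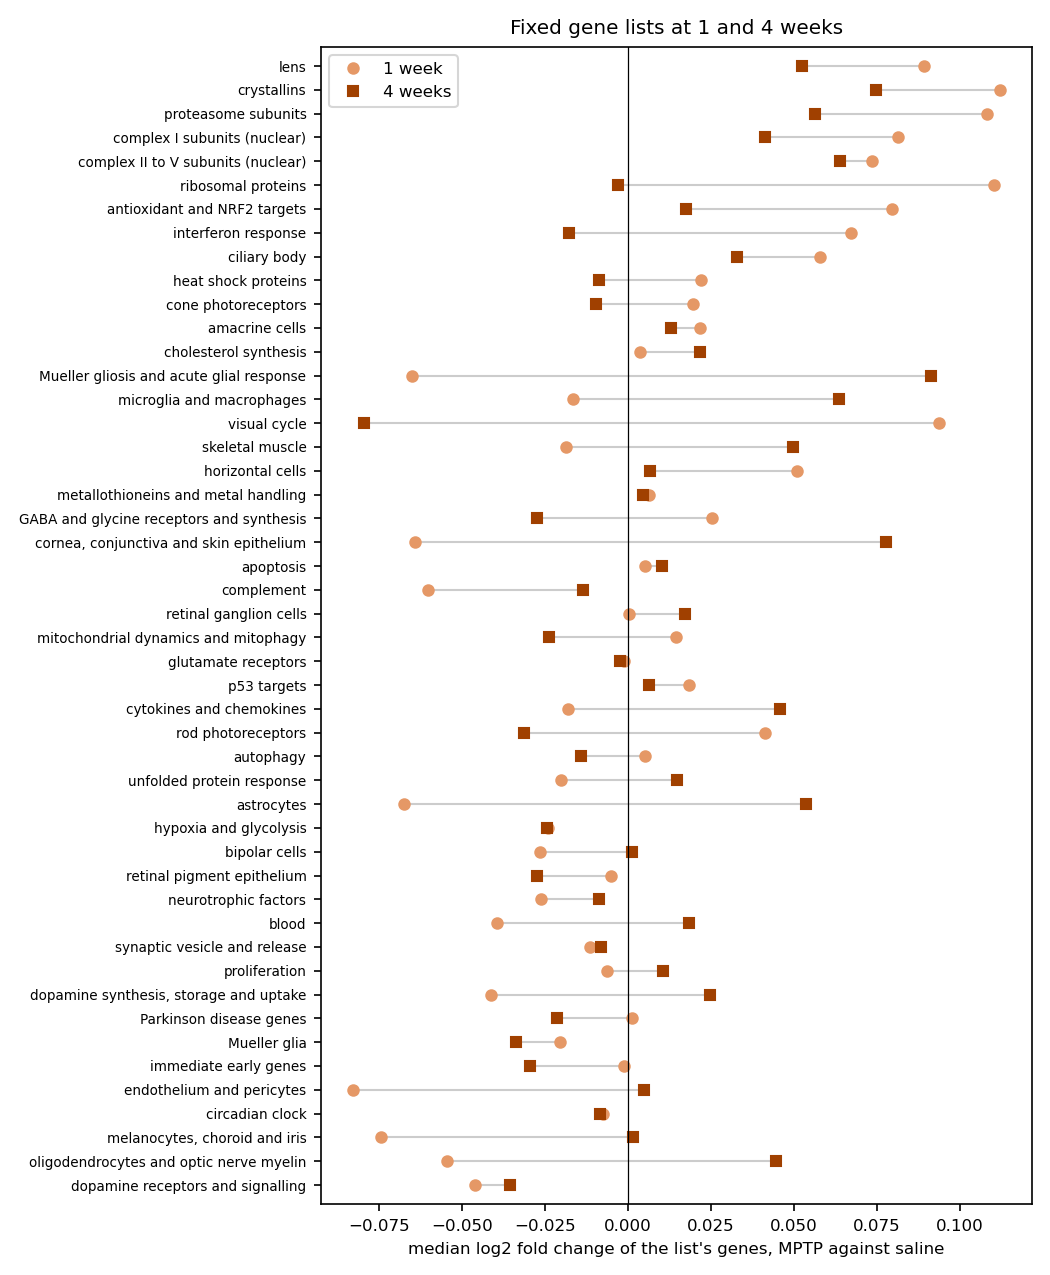
Median log2 fold change of MPTP against saline for the 48 gene lists tested (circles, 1 week; squares, 4 weeks; a grey line joins the medians of a list). The proteasome median was 0.11 at 1 week, and that of complexes II to V was 0.07 at 1 week and 0.06 at 4 weeks.

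MPTP against saline over both times asks which differences the arrays of 1 and 4 weeks share. Nuclear-encoded subunits of the respiratory chain and proteasome subunits were higher with MPTP by small amounts, with medians of 0.07 to 0.08, by camera with a preset correlation and not with an estimated one (adjusted p = 0.996 for the smallest). Uqcrh, a subunit of complex III (probe set 10515253), stood at 0.34 ± 0.07 (n = 4), and Ufm1 at 0.50 ± 0.09. Rlbp1 stood at -0.40 ± 0.08, Dio2 at -0.44 ± 0.09, and Glud1, the mitochondrial glutamate dehydrogenase, at -0.33 ± 0.06. No single gene passed over all genes.

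Of 37 subunits of complexes II to V, 28 were above 0 with a median of 0.07 (camera adjusted p = 2.14e-05). Adjusted over the list alone, 2 of them rose, Uqcrh and Uqcrb (0.27 ± 0.07), against 0 over all genes, and Cox6c stood at 0.21 ± 0.06. Of 31 proteasome subunits, 27 were above 0 with a median of 0.08 (adjusted p = 3.03e-05), with Psma4 at 0.17 ± 0.06 and Psmb3 at 0.14 ± 0.06. Of 35 complex I subunits, 27 were above 0 with a median of 0.08 (adjusted p = 0.00108), with Ndufb5 at 0.23 ± 0.07 and Ndufs4 at 0.16 ± 0.06. The median of the 26 ribosomal proteins was 0.06 with 17 above 0 (adjusted p = 0.0174), with Rpl8 at 0.18 ± 0.07 and Rps9 at 0.15 ± 0.06. None of the 4 lists passed with an estimated correlation (adjusted p = 0.996 for the smallest), and with fry the smallest adjusted p was 0.995. The first 3 lists passed with the preset correlation after quantile and after cyclic loess normalization and without any single array. The ribosomal list did not after cyclic loess (adjusted p = 0.119) or without any of the 4 arrays of 1 week in turn (adjusted p = 0.0680 to 0.262). Of the transcripts of the mitochondrial genome, 2 of 15 were measured, COX2 at 0.13 ± 0.09 and ND3 at 0.11 ± 0.08.

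The other genes highest over both times were Zfp763 at 0.47 ± 0.08, Eola1 at 0.35 ± 0.07 and Tmem229b at 0.35 ± 0.07, and the other lowest were Il1f8 at -0.39 ± 0.10 and Krtap3-2 at -0.34 ± 0.08. Uqcrh stood at percentile 99.2 of the mean signal and Glud1 at 87.6. Rlbp1 was lower in every alternative setting, from -0.48 to -0.34. It passed when adjusted over the visual cycle list alone and over the Mueller glia list alone, 1 gene in each, against 0 over all genes. Those lists as a whole had medians of 0.02 with 9 of 16 above 0 (mean -0.0019, adjusted p = 0.914) and -0.02 with 10 of 22 above 0 (adjusted p = 0.314). The rod list had a median of -0.0028 and the cone list of 0.02 in this comparison. Over both times Th stood at -0.09 ± 0.06, Slc6a3 at 0.02 ± 0.10, Ddc at -0.03 ± 0.08, Slc18a2 at -0.06 ± 0.06, Drd2 at 0.04 ± 0.06 and Drd4 at -0.08 ± 0.06. Gfap stood at 0.01 ± 0.09, Aif1 at 0.08 ± 0.11, Thy1 at -0.03 ± 0.06, Opn1sw at -0.0089 ± 0.06 and Drd1 at 6.9e-04 ± 0.06, which turned to -0.0031 when each array was centred on its median.

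**Figure D4:**
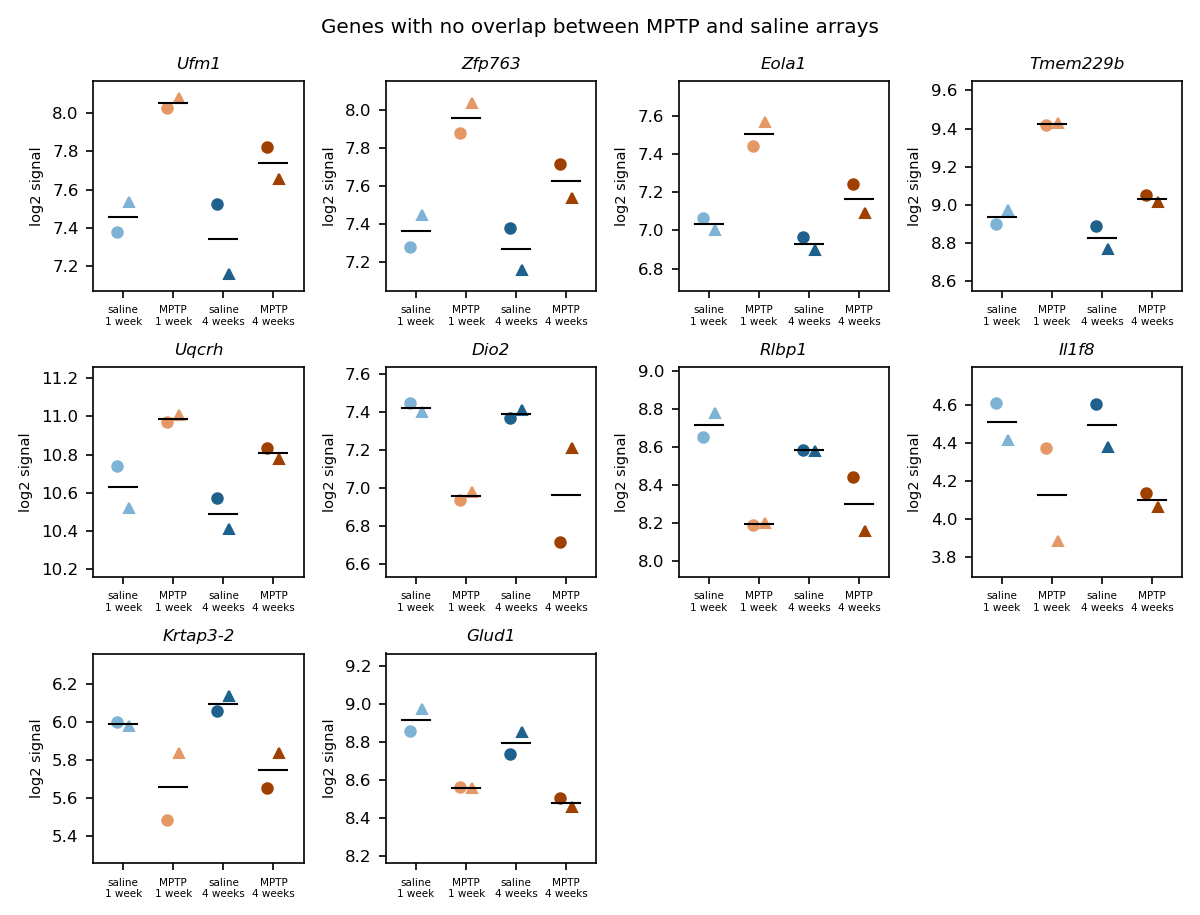
Log2 signal per array of the 5 genes highest and the 5 lowest over both times in the 4 groups (circles, array 1; triangles, array 2; lines, mean of the 2 arrays). No gene passed over all genes, with log2 fold changes from 0.50 ± 0.09 for Ufm1 to -0.44 ± 0.09 for Dio2.

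By limma 0 genes passed over both times (smallest adjusted p = 0.973, Glud1), and 950 (4.76%) had an unadjusted p under 0.05, 458 higher and 492 lower. No gene had changed 1.5-fold, and 499 genes (2.50%, against 2.86% by chance) had no overlap between the 4 MPTP and the 4 saline arrays, 202 higher and 297 lower. Without the 2 arrays that stand apart, 0 genes passed, 1176 had an unadjusted p under 0.05, 2 had changed 1.5-fold and 5 lists were called. In simulated arrays with each gene's moderated spread from the fit and genes independent of each other, 200 genes were changed, 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold. The same test recovered 83.6% of genes changed 1.5-fold at 1 week, 80.6% at 4 weeks, 26.9% for the difference of the effects and 100% over both times, and it also called 8 to 23 unchanged genes. An adjusted p depends on the other changed genes, here also those changed 2-fold and 4-fold, and real genes can shift together on an array. These shares therefore do not tell how many changes the real arrays would miss. For a simulated shift of 0.1 in the proteasome list at 1 week, camera gave an adjusted p of 0.0180 with the preset and 0.739 with an estimated correlation.

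**Figure D5:**
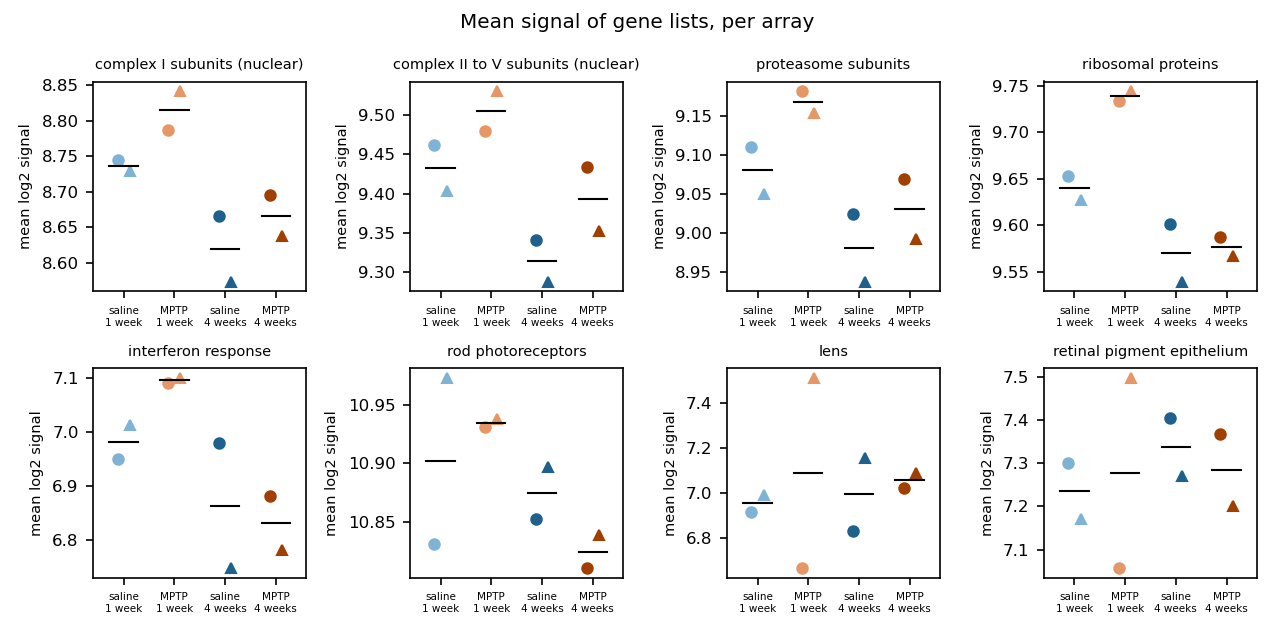
Mean log2 signal per array of 8 gene lists in the 4 groups (circles, array 1; triangles, array 2; lines, mean of the 2 arrays; axes differ between panels). In complexes II to V the MPTP arrays lie above the saline arrays within each time, and in the lens panel MPTP 1 week array 2 lies at 7.51.

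The difference of the MPTP effects (4 weeks minus 1 week) asks whether the early and the late response differ. Ribosomal proteins, interferon response genes and rod photoreceptor genes had a lower MPTP effect at 4 weeks than at 1 week, and genes of cornea, conjunctiva and skin epithelium a higher one, by camera with a preset correlation. None of the 4 calls held with an estimated correlation (adjusted p = 0.975 for the smallest), and only that of the interferon list held after quantile and cyclic loess normalization. The interferon-induced genes Rtp4 (-0.77 ± 0.14), Xaf1 (-0.64 ± 0.21) and Ifi203 (-0.59 ± 0.21) were among the lowest 5. No single gene passed over all genes.

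The median difference was -0.10 for the ribosomal proteins (20 of 26 below 0, camera adjusted p = 0.0101), -0.13 for the interferon response genes (17 of 25 below 0, adjusted p = 0.0149), and -0.06 for the rod genes (22 of 25 below 0, adjusted p = 0.0149). It was 0.11 for the cornea, conjunctiva and skin list (12 of 16 above 0, adjusted p = 0.0226). Examples were Gngt1 at -0.22 ± 0.13 and Tulp1 at -0.19 ± 0.15 among rod genes, and Sprr1b at 0.69 ± 0.20, Krt15 at 0.53 ± 0.23 and Sfn at 0.32 ± 0.14 among epithelial genes. With an estimated correlation none passed (adjusted p = 0.975 for the smallest), and with fry the smallest adjusted p was 0.995. The calls of the ribosomal, rod and epithelial lists ended after quantile and cyclic loess normalization, and that of the interferon list remained. With each array left out in turn, the interferon median ranged from -0.17 to -0.068. The rod median then ranged from -0.16 to -0.0018 and the epithelial median from 0.0040 to 0.23. Rny1 (-0.87 ± 0.37) and Klk1b9 (-0.69 ± 0.30) were the other lowest genes, and Glipr1l1 (0.89 ± 0.12), Ccr1l1 (0.85 ± 0.26), Clec2e (0.81 ± 0.18), Rad21l (0.76 ± 0.24) and Rdh7 (0.76 ± 0.27) the highest.

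By limma 0 genes passed for the difference (smallest adjusted p = 0.147, Gm5039), and 391 (1.96%) had an unadjusted p under 0.05, 284 higher and 107 lower. In all, 43 genes had changed 1.5-fold, 33 higher and 10 lower. Without the 2 arrays that stand apart, 0 genes passed, 1346 had an unadjusted p under 0.05, 182 had changed 1.5-fold and 9 lists were called. Across genes, which are not independent replicates, the effects at 1 and 4 weeks correlated with a Pearson r of 0.145 and a Spearman rank correlation of 0.142, and 54.8% of genes had the same sign. Other groupings of the same arrays gave absolute values of r up to 0.301, and without saline 1 week array 2 or MPTP 1 week array 2 the correlation was -0.06 or -0.04.

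The saline groups at 4 weeks against 1 week show how the control retina differed with time, which holds the age of the mice and any difference in handling dates. Nuclear-encoded subunits of the respiratory chain and proteasome subunits had lower signal at 4 weeks in nearly all members, by camera with a preset correlation and not with an estimated one (adjusted p = 0.535 for the smallest). The interferon-related genes B2m, the light chain of class I molecules (-0.51 ± 0.21), and Gbp4 (-0.50 ± 0.15) were among the lowest 5, and the potassium channel Kcnj13 was highest at 0.51 ± 0.16. Most of the B2m difference came from saline 4 weeks array 2, at 9.53 against 10.16 in array 1, with 10.46 and 10.25 at 1 week. The MPTP arrays of 4 weeks had a like gap, 10.18 in array 1 and 9.66 in array 2. No single gene passed.

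In saline retinas, 36 of 37 subunits of complexes II to V were below 0 with a median of -0.13 (camera adjusted p = 3.10e-09), and 32 of 35 complex I subunits with a median of -0.13 (adjusted p = 9.55e-09). So were 30 of 31 proteasome subunits with a median of -0.10 (adjusted p = 6.65e-07). Examples were Uqcrq at -0.25 ± 0.11, Ndufs8 at -0.24 ± 0.09 and Ndufa11 at -0.26 ± 0.12. Of 48 lists 13 were called, 10 lower and 3 higher. The other lower lists had medians from -0.12 (cone photoreceptors) to -0.05 (hypoxia and glycolysis) and included the ribosomal proteins at -0.10, with Rplp1 at -0.23 ± 0.09, and the interferon response at -0.10. The higher lists were immediate early genes at 0.04, skeletal muscle at 0.06, and oligodendrocytes and optic nerve myelin at 0.08, with all 12 myelin genes above 0. Without saline 1 week array 2 these medians were 0.0067, 0.0043 and 0.027, and none of the 3 lists passed. None passed with an estimated correlation (adjusted p = 0.535 for the smallest), and with fry the smallest adjusted p was 0.264. After quantile or cyclic loess normalization 4 lists were called, the 3 lists of the respiratory chain and proteasome and the interferon response. Without saline 1 week array 2, 5 lists were called, with the interferon response among the lists lost (adjusted p = 0.472). The ribosomal and interferon calls also ended without saline 4 weeks array 2 (adjusted p = 0.192 and 0.858).

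The remaining named genes were AF366264 at 0.47 ± 0.18, Gal3st2c at 0.43 ± 0.11, Atoh1 at 0.41 ± 0.17 and Cyp4a12a at 0.41 ± 0.10 on the high side, and Zfp874b at -0.60 ± 0.15, Zfp979 at -0.51 ± 0.16 and Cd209f at -0.50 ± 0.12 on the low side. By limma 0 genes passed (smallest adjusted p = 1.00), and 424 (2.13%) had an unadjusted p under 0.05, 174 higher and 250 lower. Of these, 2 had changed 1.5-fold, Zfp874b and the olfactory receptor Olfr243 (-0.72 ± 0.24), the latter named after its value was seen. Without the 2 arrays that stand apart, 0 genes passed, 1123 had an unadjusted p under 0.05, 22 had changed 1.5-fold and 5 lists were called.

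The MPTP groups at 4 weeks against 1 week held the largest number of genes at unadjusted p under 0.05 of the 6 comparisons, 1952, a rank that did not hold with every single array left out. Their fold changes also followed signal level most closely of the 6 (Spearman rank correlation -0.519). The interquartile range of log2 signal was 2.08 and 1.95 in the MPTP arrays of 1 week, against 1.87 and 1.84 in those of 4 weeks. Interferon response genes were lower at 4 weeks, with a median of -0.20, as were ribosomal proteins at -0.15 and proteasome subunits at -0.14, by camera with a preset correlation and not with an estimated one (adjusted p = 0.429 for the smallest). The proteasome call also ended after quantile and cyclic loess normalization, which leaves a trend with signal level open for that list. Rny1 (-1.16 ± 0.26), Ifitm3 (-1.06 ± 0.32), Ifit3b (-0.90 ± 0.27), Zfp931 (-0.89 ± 0.24) and Penk, the precursor of enkephalins (-0.88 ± 0.31), were the lowest genes. Most of the Ifitm3 difference came from MPTP 4 weeks array 2, at 7.75 against 8.68 in array 1, with 9.14 and 9.41 at 1 week. The saline arrays of 4 weeks had a like gap, 8.59 in array 1 and 7.62 in array 2. No single gene passed over all genes.

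Of 25 interferon response genes 19 were below 0 (camera adjusted p = 1.80e-05), and adjusted over the list alone 8 fell, against 0 over all genes. Among them were Xaf1 at -0.74 ± 0.15, Ifit3 at -0.87 ± 0.23, Gbp3 at -0.67 ± 0.18 and Iigp1 at -0.46 ± 0.13. The mean of the interferon list was 7.09 and 7.10 in the MPTP arrays of 1 week and 6.88 and 6.78 in those of 4 weeks, against 6.95 and 7.01 in saline at 1 week and 6.98 and 6.75 in saline at 4 weeks. Of 26 ribosomal proteins 25 were below 0 (adjusted p = 1.03e-07), and adjusted over the list alone 3 fell, against 0 over all genes, namely Rpl19 (-0.36 ± 0.08), Rpl30 (-0.38 ± 0.10) and Rpl7 (-0.34 ± 0.09). All 31 proteasome subunits (adjusted p = 2.90e-07), 34 of 35 complex I subunits (adjusted p = 1.03e-07) and all 25 rod genes (adjusted p = 1.57e-04) were below 0. Examples were Psmb1 at -0.25 ± 0.09, Ndufb2 at -0.36 ± 0.09, Ndufb5 at -0.39 ± 0.10 and Tulp1 at -0.26 ± 0.10. Of 16 genes of cornea, conjunctiva and skin epithelium, 14 were above 0 with a median of 0.18 (adjusted p = 2.24e-04), and adjusted over the list alone 1 rose, Sfn (0.39 ± 0.10), against 0 over all genes. In all, 15 lists were called, 5 higher and 10 lower, with Mueller gliosis (0.17), muscle (0.15), myelin (0.14) and microglia (0.11) among the higher ones.

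None of the 15 lists passed with an estimated correlation (adjusted p = 0.429 for the smallest), and with fry the smallest adjusted p was 0.0505. After quantile or cyclic loess normalization 3 were called, the ribosomal, interferon and epithelial lists, and the median of complexes II to V, -0.09 as deposited, was 6.6e-04 after cyclic loess. The median of Mueller gliosis was -0.04 without MPTP 4 weeks array 1 (adjusted p = 0.596). The microglia median was 0.031 (adjusted p = 0.311) and the myelin median 0.078 (adjusted p = 0.457) without MPTP 1 week array 1, and both calls also ended without MPTP 4 weeks array 1 (adjusted p = 0.0875 for each) and that of microglia without MPTP 4 weeks array 2 (adjusted p = 0.0502). The epithelial genes are markers of another tissue, and the 2 arrays that stand apart include 1 of the MPTP arrays at 1 week. The genes with the highest fold changes were Cyp2d11 at 0.71 ± 0.20, Rnu5g at 0.65 ± 0.22, Stfa3 at 0.64 ± 0.12, Cyp2c67 at 0.61 ± 0.10 and Uox at 0.60 ± 0.15. By limma 0 genes passed (smallest adjusted p = 0.507), 1952 (9.79%) had an unadjusted p under 0.05, 1083 higher and 869 lower, and 32 had changed 1.5-fold, 10 higher and 22 lower. Without the 2 arrays that stand apart 1 gene passed, Rny1 at -1.69 (adjusted p = 0.0374), 1871 had an unadjusted p under 0.05, 63 had changed 1.5-fold and 18 lists were called. Without MPTP 1 week array 1 alone Rny1 also passed (adjusted p = 0.0117), while without MPTP 1 week array 2 it stood at -0.64 and did not pass.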

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

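Chosen only after the result was seen were the tests of other tissues and of exchanged labels for the 2 arrays that stand apart, the tests of lists after cyclic loess normalization, the test of photoreceptor share, the count of arrays whose removal ends the interferon call, and the split counts at the adjusted threshold and for 1.5-fold changes. The test of signal range for the 2 arrays was chosen after they were seen to stand apart and before its own result was seen.

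Saline 1 week array 2 and MPTP 1 week array 1 stood apart from the other 6 arrays. A trend with signal level between arrays as the whole cause is argued against, since setting these 2 arrays against the other 2 at 1 week still gave 2945 genes at unadjusted p under 0.05 after cyclic loess normalization (4235 before it), against 1022 in the next split. RNA of other eye tissues stays open: among 8 such lists the largest median difference was -0.26 for the lens, whose means overlapped between the 2 pairs, and the largest without overlap was -0.13 for the pigment epithelium, against a median absolute difference of 0.264 among the genes at unadjusted p under 0.05 in that split, with a bound set after the value had been seen. An exchange of a saline and an MPTP array at 1 week stays open too. After cyclic loess normalization the correlation of the effects at 1 and 4 weeks was 0.231 under 1 exchange that brings them together (its mirror image has the opposite sign) and 0.194 as labelled. The gap was smaller than 0.145, the SD of the labelled correlation with each array left out in turn. That SD was taken from the deposited values and is not the spread of the gap itself. Each has a group mate that does not stand apart, so the groups of the design do not set them apart, and no biological explanation was tested.

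Over both times the lists of complex I, complexes II to V and the proteasome were higher with MPTP. Fold changes in this comparison hardly followed signal level across genes (Spearman rank correlation 0.019). That value argues against a trend with signal level as the whole cause for the 3 lists. Cyclic loess normalization had little such trend to remove, so the calls kept after it add little. Their largest adjusted p by camera with the preset correlation was then 0.00253. The ribosomal call ended after it (adjusted p = 0.119, median 0.06 before and 0.05 after), which leaves a trend open for that list. A larger share of photoreceptors, which are rich in mitochondria, was not seen in the rod list. Its median was -0.0028, and its mean was 10.88 with MPTP and 10.89 with saline. The explanation stays open, since the SD of the rod mean across arrays was 0.06 in each treatment. The cone median was 0.023, and members of both lists went either way. The mean of the rod list at 4 weeks was 10.81 and 10.84 in the MPTP arrays, below 10.85 and 10.90 in saline. At 1 week it was 10.93 and 10.94 in MPTP, between 10.83 and 10.97 in saline. None of these lists passed with an estimated correlation (adjusted p = 0.996 for the smallest). That test also missed a simulated shift of 0.1 in the proteasome list at 1 week (adjusted p = 0.739). No such simulation was run over both times, so how much the miss there counts against the lists is not known. Chance stays open as well, since 30 of the 35 splits of the arrays into 4 and 4, the real one included, gave as many called lists (real 4). That count does not tell how often these same lists were called. The effect of MPTP itself is among the open explanations and was not tested apart from these.

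The difference of the MPTP effects was lower for the interferon response, with a median of -0.13, by the test of the difference itself with the preset correlation, and not with an estimated one (adjusted p = 0.975). A trend with signal level as the whole cause is argued against, since the adjusted p was 0.0306 after cyclic loess normalization. That single arrays set the value stays open, since the call ended without 4 of the 8 arrays, namely saline 1 week array 1 (adjusted p = 0.254), MPTP 1 week array 2 (0.0668), saline 4 weeks array 1 (0.718) and MPTP 4 weeks array 2 (0.170), with medians over each of the 8 left out from -0.17 to -0.068. A response to MPTP that differs between the times is consistent with the values and was not tested apart from this.

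The difference of the MPTP effects was also called for the ribosomal proteins at -0.10, and the call ended after cyclic loess (adjusted p = 0.350) and without saline 1 week array 2 (0.0704), MPTP 1 week array 2 (0.0598) or saline 4 weeks array 1 (0.174), with medians over each of the 8 left out from -0.13 to -0.061. For the rod photoreceptor genes it was called at -0.063, and the call ended after cyclic loess (0.371) and without saline 1 week array 1 (0.965), MPTP 1 week array 2 (0.0668), saline 4 weeks array 2 (0.0985) or MPTP 4 weeks array 1 (0.0621), with medians over each of the 8 left out from -0.16 to -0.0018, the latter without saline 1 week array 1. For genes of cornea, conjunctiva and skin epithelium it was called at 0.11, and the call ended after cyclic loess (0.112) and without saline 1 week array 1 (0.797), MPTP 1 week array 1 (0.278), saline 4 weeks array 1 (0.419) or MPTP 4 weeks array 2 (0.170), with medians over each of the 8 left out from 0.0040, without saline 1 week array 1, to 0.23. None of these 3 lists passed with an estimated correlation (adjusted p = 0.975 for each).

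Chance cannot be excluded for the counts of genes at unadjusted p under 0.05 and of lists over both times. Of the 35 splits of the 8 arrays into 4 and 4, the real one included, 14 gave as many genes at unadjusted p under 0.05 (real 950, highest other 3466) and 30 as many lists (real 4, highest other 16). The real counts at the adjusted threshold (highest other 1) and of 1.5-fold changes (highest other 11) are 0, which all 35 splits reach by construction, so these say nothing about chance. The 15 splits that keep the 2 arrays that stand apart together gave from 486 to 3466 genes and the other 20, the real one included, from 295 to 2013. The 4 highest counts, 3466, 2708, 2284 and 2282, came from the former, which points to a structure of the samples other than treatment, and the split with 2284 is that of time, fitted without time as a term.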

How the results depend on the processing

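Cyclic loess normalization, leaving out the 2 arrays that stand apart and the crossed block were chosen after the data were seen. Counts of genes at the adjusted threshold stayed as reported in 110 cases under the alternatives and were higher in 2. Of the values of named genes, 1994 kept their direction and their side of the threshold, though not always their size, 2 (Rny1 with time in MPTP) kept their direction and passed the threshold, and 45 were reversed, all among the fixed dopamine system and cell marker genes. The number of arrays limits the precision. A lone array left in a group is assumed to vary like the other groups, and by construction a lone array meets the rule of no overlap more easily, which raises counts of 1.5-fold changes. Where nothing else is said, the cause was not tested.

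With each array centred on its median, 4 genes had changed 1.5-fold with time in saline, and Drd1 over both times was -0.0031. With the filter on dim genes, which tests fewer genes by construction, the counts changed 1.5-fold were 3 at 1 week, 0 at 4 weeks, 5 for the difference, 1 with time in saline and 10 with time in MPTP. Lists called were then 3 at 4 weeks, 1 for the difference and 5 with time in MPTP, and the correlation of the effects at 1 and 4 weeks was 0.315. With all probe sets, 1 gene had changed 1.5-fold over both times. With an estimated correlation and with fry, 0 lists were called in each of the 6 comparisons. After quantile normalization lists called were 0 at 1 week, 3 at 4 weeks, 1 for the difference, 4 with time in saline and 3 with time in MPTP, and Drd4 at 1 week was -0.0201. After cyclic loess normalization lists called were again 0, 3, 1, 4 and 3, Drd4 at 1 week was -0.0192, and the median of complexes II to V with time in MPTP was 6.6e-04.

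Without the 2 arrays that stand apart, genes changed 1.5-fold were 138 at 1 week, 182 for the difference, 22 with time in saline, 63 with time in MPTP and 2 over both times, 1 gene passed with time in MPTP, and lists called were 11 at 1 week, 9 for the difference and 5 with time in saline. Drd4 (-0.0205), Slc18a2 (0.0087) and Aif1 (-0.068) at 1 week and Thy1 over both times (0.012) changed sign.

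Across genes, the deviations of same-numbered arrays correlated between -0.383 and 0.207, at 0.119 for saline and MPTP at 4 weeks. Single lists did differ by number in both treatments at 4 weeks, in either direction. The Mueller gliosis list had means of 7.31 and 6.96 in saline arrays 1 and 2, and of 7.42 and 7.01 in MPTP. The lens list had 6.83 and 7.16 in saline, and 7.02 and 7.09 in MPTP. Saline and MPTP 4 weeks array 2 correlated best with each other (r = 0.996). The replicate block gave 0 genes at the adjusted threshold in all 6 comparisons, with 8 lists called at 1 week. The crossed block gave 0 genes at the adjusted threshold in all 6 comparisons.

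With each array left out in turn, genes changed 1.5-fold ranged from 14 to 92 at 1 week, highest without saline 1 week array 2 (63, 62 and 26 without MPTP array 1, MPTP array 2 and saline array 1 of that time). They ranged from 2 to 40 at 4 weeks, highest without MPTP 4 weeks array 2 (15, 11 and 11 without the other 3 of that time), from 58 to 168 for the difference, highest without saline 1 week array 2 (137 and 108 without MPTP 1 week array 2 and MPTP 4 weeks array 1). They also ranged from 2 to 44 with time in saline, highest without saline 1 week array 1, from 32 to 146 with time in MPTP, highest without MPTP 1 week array 2, and from 0 to 5 over both times. Genes at unadjusted p under 0.05 ranged from 631 to 1876 at 1 week (highest without saline 1 week array 2), from 215 to 678 at 4 weeks (lowest without saline 4 weeks array 2, highest without MPTP 4 weeks array 2), and from 222 to 1445 for the difference (lowest without saline 4 weeks array 1, highest without saline 1 week array 2). They ranged from 198 to 1688 with time in saline (lowest without saline 4 weeks array 2, highest without saline 1 week array 1), from 1110 to 3141 with time in MPTP (lowest and highest without MPTP 1 week arrays 1 and 2), and from 597 to 1604 over both times (lowest without saline 4 weeks array 2, highest without saline 1 week array 1). Lists called ranged from 3 to 8 at 1 week, 1 to 5 at 4 weeks, 2 to 9 for the difference, 5 to 16 with time in saline and 3 to 7 over both times, genes at the adjusted threshold with time in MPTP from 0 to 1, and the correlation of the effects from -0.060 to 0.310. The median of Mueller gliosis with time in MPTP ranged from -0.045 to 0.24.

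Single genes with a sign that turned when an array was left out ranged as follows. At 1 week Slc6a3 lay between -0.27 and 0.10, Slc18a2 between -0.13 and 0.0013, Drd4 between -0.043 and 0.048, Gfap between -0.20 and 1.5e-04, Opn1sw between -0.076 and 0.058, and Aif1 between -0.16 and 0.40. At 4 weeks Th lay between -0.094 and 0.057, Ddc between -0.15 and 0.12, Drd1 between -0.0075 and 0.12, Drd2 between -0.028 and 0.063, Gfap between -0.044 and 0.28, Opn1sw between -0.042 and 0.025, Thy1 between -0.012 and 0.055, and Aif1 between -0.0014 and 0.072. Over both times Slc6a3 lay between -0.033 and 0.12, Ddc between -0.087 and 0.019, Drd1 between -0.035 and 0.021, Gfap between -0.076 and 0.071, Opn1sw between -0.036 and 0.018, and Aif1 between -0.041 and 0.18.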

Other observations

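The exact tests on the mean of a list per array were chosen only after the lists had been seen. Several members of lists not called over both times had values of about 3 standard errors or more over both times without passing over all genes. They were picked for their size among all members of these lists. Of all genes, 4.76% had an unadjusted p under 0.05 by limma in this comparison, against 5% expected by chance. Chance can therefore account for such values. Among genes of glycolysis, the neuronal enolase Eno2 stood at -0.24 ± 0.08 and the lactate dehydrogenase subunit Ldha at -0.19 ± 0.06 (n = 4), while the hypoxia and glycolysis list as a whole had a median of -0.0062 with 16 of 26 below 0 (camera adjusted p = 0.553). Among genes of the glutathione system, Gclc, a subunit of the enzyme that makes the precursor of glutathione, stood at -0.22 ± 0.07, while the antioxidant list ran the other way with a median of 0.05 and 18 of 26 above 0 (adjusted p = 0.172). Nrn1, a marker of ganglion cells, stood at -0.30 ± 0.08, against a median of 0.0036 in the list of 21 ganglion cell genes (adjusted p = 0.970). In the cytokine list, Il33 stood at 0.22 ± 0.06 and Ccl3 at -0.20 ± 0.06, with 14 of 29 genes above 0. Cycs, which encodes cytochrome c, stood at 0.22 ± 0.06, against a median of 0.0052 in the apoptosis list (adjusted p = 0.890). The outer segment gene Rom1 stood at 0.20 ± 0.06, against a median of -0.0028 in the rod list (adjusted p = 0.990).

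With the mean of each list per array as the unit, 2 of 48 lists had no overlap between MPTP and saline arrays within both times in the same direction, against 2.67 expected by chance for either direction together. These were complexes II to V and apoptosis, both higher with MPTP. The exact permutation test within times cannot give a p below 0.0556, and both lists reached it. Without regard to time the exact permutation test of 4 against 4 arrays gave 0.0286 for apoptosis (difference 0.02), the smallest p it can give, with an adjusted p of 1, and a larger p for complexes II to V (difference 0.08).

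The 7155 probe sets without a single gene name were fitted in the same way with limma, and 0 passed the adjusted threshold in any of the 6 comparisons. Those with an unadjusted p under 0.05 numbered 325 at 1 week, 227 at 4 weeks, 121 for the difference, 176 with time in saline, 586 with time in MPTP and 450 over both times.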
